A study of Mus musculus and Homo sapiens with 18 samples.

How the data were processed

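HA-tagged dCas9 was immunoprecipitated with an anti-HA antibody and the DNA sequenced, in mouse V6.5 ES cells and human 293FT cells; input samples had no antibody. Per the submitters' processing notes, reads were mapped with Bowtie, for which no version is given, and the builds were mm9 for mouse and hg19 for human. The names of the deposited peaks begin with MACS, a peak caller; its version, the control library, the threshold and any filter are not given in the sources used here. Peak lists of 16 of the 18 samples were used, 1 list for each. The names of 12 of the 16 deposited lists call them filtered, and the lists hold fewer peaks than the running numbers in their names, so peaks were removed by a rule that is not given. Some peak names recur within a list, for a reason that was not tested. Each deposited peak has a position and a score; the score is the authors' and its column has no name. The lowest score in any list was 50.01. The score was used to describe, rank or filter peaks within a list. Scores of 1 position are printed side by side for several lists without a test of change. Shares of EMX1 peaks above the highest control scores are given without a test. Correlations of scores between lists are over paired peaks. In 12 lists the sixth column was a whole number, which has no stated meaning and was not used as a measurement. The Phc1 lists, Nanog-sg2 at 20 ug and the first Nanog-sg3 20 ug library lacked this column. It held 5 in the transient lists, 10 in the other Nanog-sg3 lists and 11 for Nanog-sg2 at 10 and 40 ug. In the human lists it held 3, with 2 at 1 peak of each EMX1 list. Lists compared here may thus not have been prepared alike. Starts were taken to count from 0 and are printed counting from 1.

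Samples were grouped by guide, dose, cell line and IP or input from the labels. The library whose title names 20 ug stood for 20 ug in the Nanog-sg3 dose series (replicate 2), and the other 20 ug library was replicate 1. These were taken as separate libraries because the labels list them as separate samples; 0 of their peaks had the same start and end, so the lists are not copies. Depth per sample is unknown because the lists carry no read or tag counts, and intervals on shares (exact Clopper-Pearson, 95%) cover counting error only. Peaks with at least 1 bp in common were called shared. For chance, 1 list of a pair was shifted along each chromosome by a random distance, wrapping around the span covered by all lists, 1000 times, giving a one-sided p that was adjusted by Benjamini-Hochberg over the 66 mouse or 6 human pairs. Median scores of shared and unshared peaks were compared by a two-sided permutation test with 100000 draws (all splits where these were few), adjusted over 36 comparisons, and scores of shared peaks by Pearson r and Spearman rho on log scores with permuted pairings (every pairing for fewer than 10 peaks), for pairs with at least 6 shared peaks. Chromosome distributions of lists with at least 100 peaks were compared by a chi-square with 10000 Monte Carlo draws, adjusted over 11 pairs; the smallest p these draws can give is 1.0e-04. The shift test for more overlap was tested on simulated data for the 0.2 ug list against the second 20 ug library, with fewer shifts. It called 0 of 40 lists placed at random and 40 of 40 lists with 10 of 166 peaks planted. The random peaks were placed without clustering, and planted peaks were exact copies of peaks in the other list. Clustered lists, lists of other sizes and the test for fewer overlaps were not simulated.

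The samples, tests, alternatives and the rule for named positions were set before the data were examined. By that rule the text names the position at the guide's gene, peaks among the 5 strongest of a list, control peaks that overlap a guide's peak (there were none) and Nanog-sg2 positions found at 2 or more doses. The gene's position was taken from the peak shared by both guides for that gene, because no annotation of mm9 or hg19 was used here. Chosen after the lists had been examined were the requirement of the gene's known chromosome, the test for fewer overlaps, the counts over the 100 strongest peaks and over 4 score groups, and the highest number in the peak names. The positions that 2 guides shared outside their gene were also named after their values were seen. Chromosomes 4, 17, 19 and 22, named for the EMX1 guides, were not part of the rule set in advance. The alternatives were a minimum score of 95.15 (the median over all lists) and of 100, merging of peaks within 500 bp, sharing of 50% of both peaks or centres within 200 bp, random placement as chance, a 1 kb window around control peaks, and leaving out each 20 ug replicate. Fold enrichment, tag counts, false discovery rates and summits were not used here, so the score stood in for strength and centres for summits. The planned tests of guide-proximal sequence next to a protospacer motif and of genes near peaks were not run, since no genome or annotation of the builds was used here. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used.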

Results

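Binding of catalytically inactive Cas9 (dCas9) to the genome was measured by chromatin immunoprecipitation with an antibody against its HA tag, followed by sequencing (ChIP-seq). dCas9 keeps the RNA-guided DNA binding of Cas9 but does not cut, so a peak marks where the protein was held. Mouse V6.5 cells are embryonic stem (ES) cells; most of these libraries came from a V6.5 line with a stably integrated dCas9 gene, transfected with 1 single guide RNA (sgRNA). Nanog encodes a homeobox transcription factor of pluripotent cells, and Phc1 a subunit of Polycomb repressive complexes. 293FT, a human embryonic kidney cell line, was used with guides for EMX1, a homeobox gene of the developing forebrain. The 18 samples comprised 6 guides, a dose series for each Nanog guide, a transient dCas9 arm, and no-sgRNA and input controls. Peak lists of 16 samples were used, 12 from mouse and 4 from human cells; lists for the mouse no-sgRNA immunoprecipitate (IP) and the Phc1-sg1 input were not analysed here. Each group held 1 library except Nanog-sg3 at 20 ug in stable cells, which held 2. Read depth is unknown, since the lists carry no read counts, and no annotation of the builds was used here, so peaks are given by position only.

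Guides differed widely in how many sites they gave. At 20 ug, Nanog-sg3 gave 5909.5 ± 67.2 peaks (mean ± SD, n = 2 libraries of 5957 and 5862), whereas Nanog-sg2, directed at the same gene in the same cells, gave 26. Phc1-sg1 gave 2948 peaks and Phc1-sg2 gave 663, a ratio of 4.45. In 293FT cells EMX1-sg1 gave 18042 peaks and EMX1-sg3 gave 853, a ratio of 21.2. The no-sgRNA IP of 293FT cells gave 63 peaks and the matching input 49, with numbers in the peak names up to 2277 and 461. Differences between guides rest mostly on single libraries and carry no test. The only SD available, 67.2 peaks for Nanog-sg3 at 20 ug, is of 2 counts after the filter. Those 2 lists differ in format, and the numbers in their peak names ran to 13680 and 15070. The SD is thus no measure against which the guides can be compared. The numbers also depend on a filter whose rule is not given in the sources used here: the running numbers in the peak names reached 24057 for EMX1-sg1 and 20115 for EMX1-sg3, 14292 for Phc1-sg1 and 2151 for Phc1-sg2, and 13680 and 1734 for Nanog-sg3 (first library) and Nanog-sg2 at 20 ug, so the gap between the EMX1 guides in the lists was nearly absent from the numbering.

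The sites the guides were made for were sought as positions called with both guides for a gene, on the chromosome where that gene is known to lie. Both Phc1 guides had their highest-scoring peak at chromosome 6 between 122290175 and 122292993 (mm9), with the authors' peak score at 1463.16 for Phc1-sg1 and 1606.98 for Phc1-sg2. Nanog-sg2 at 20 ug and the first Nanog-sg3 library at 20 ug shared a peak on chromosome 6 between 122655719 and 122658343, which lay 362.7 kb from the Phc1 position. It ranked 1 of 26 for Nanog-sg2, with a score of 1200.13 against 352.90 for the next peak, and 5 of 5957 for Nanog-sg3, with a score of 1472.86. The EMX1 guides shared a peak on chromosome 2 between 73160459 and 73161547 (hg19), ranked 4 of 853 for EMX1-sg3 (score 565.18) and 398 of 18042 for EMX1-sg1 (score 473.91). For 3 of the 6 guides, Nanog-sg3, EMX1-sg1 and EMX1-sg3, peaks elsewhere thus scored above the peak at the named gene. None of the 3 control lists had a peak at these positions. The Nanog position had no peak in the 7 other lists of Nanog-guide IPs, which include the second 20 ug library and the transient library of Nanog-sg3. Both Nanog lists with the peak lack the sixth column, which all 7 without it have, so its absence goes with the format of the lists. The filter rule is not given, so this absence cannot be read as a lack of binding.

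**Figure D1:**
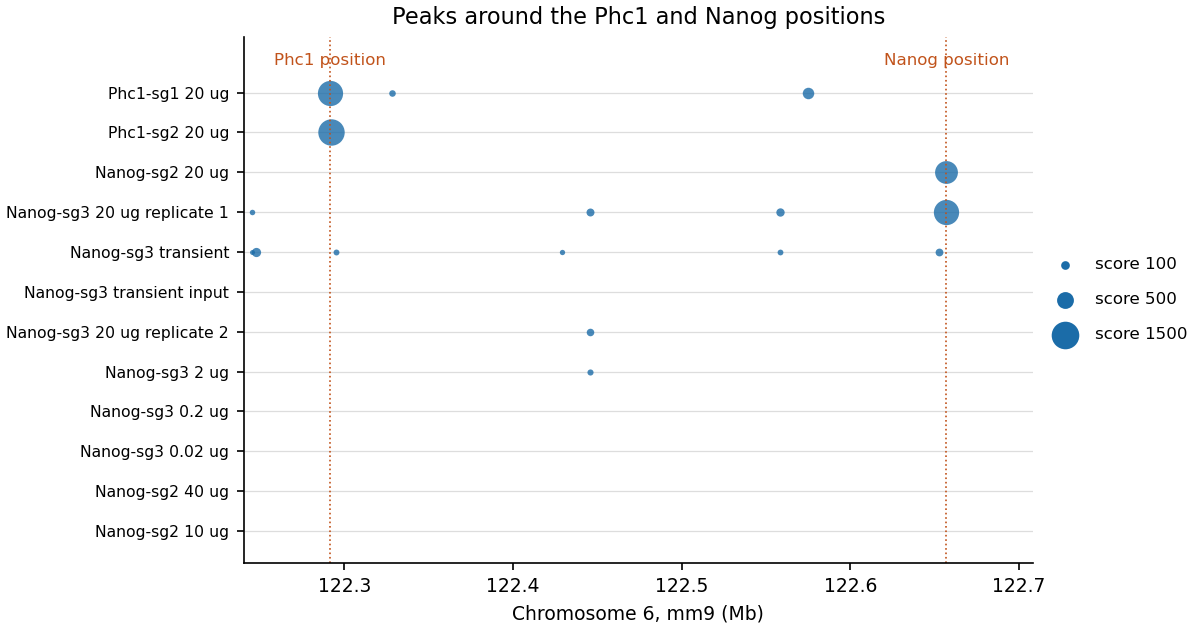
Peaks on chromosome 6 (mm9, x axis in Mb) around the Phc1 and Nanog positions (dotted lines), 1 row per mouse list; each dot is a peak and its area is proportional to the authors' peak score. In the deposited lists, whose filter rule is not given, the Phc1 position carried a peak in both Phc1 lists (1463.16 and 1606.98). The Nanog position carried one in 2 of the 9 Nanog-guide IP lists (1200.13 and 1472.86).

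In the deposited lists the strongest peaks away from the named genes were different for each guide. For Phc1-sg1 they lay at chromosome 9 between 62629435 and 62630453 (score 1319.63) and chromosome 5 between 74720477 and 74720944 (1268.88). For Phc1-sg2 they lay at chromosome 4 between 21749522 and 21750635 (1240.49) and chromosome 2 between 51892297 and 51893088 (1222.29). The highest EMX1-sg1 peak was at chromosome 12 between 31269995 and 31273523 (2927.50), and the highest EMX1-sg3 peak at chromosome 3 between 43197021 and 43197845 (966.01). No list of another guide had a peak at any of these 6 positions.

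The Nanog-sg3 dose series asked how the sites change with the amount of guide. Stable dCas9 cells gave 122 peaks at 0.02 ug, 166 at 0.2 ug, 2698 at 2 ug and 5862 in the library titled 20 ug. The step from 0.2 to 2 ug was 16.3-fold, against 1.36-fold for the step before it and 2.17-fold for the step after it. Of the 0.2 ug peaks, 62% were found at 2 ug (103 of 166, exact Clopper-Pearson 95% interval 54.2 to 69.5%), and of the 2 ug peaks 67.1% were found at 20 ug (1811 of 2698, 65.3 to 68.9%). Where 50% of both peaks had to be shared, instead of 1 bp, these shares were 57.8% and 29.9%. Only 7.38% of the 0.02 ug peaks were found at 0.2 ug (9 of 122, 3.43 to 13.5%), and 34.4% in any other Nanog-sg3 list (42 of 122, 26.1 to 43.6%). The overlap of each pair of lists exceeded that in all 1000 circular shifts of 1 list along the chromosomes (permutation by shifts, adjusted p = 0.0037, the raw p of 0.001 being the smallest possible). Each dose held 1 library except 20 ug, which held 2, and no test over doses was made. With a score of at least 95.15 the step from 0.2 to 2 ug was 25.7-fold. The numbers in the peak names ran to 13697, 12010, 15561 and 15070 from 0.02 to 20 ug, so the steps between doses are in the numbers after a filter of unstated rule and hardly in the numbering.

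**Figure D2:**
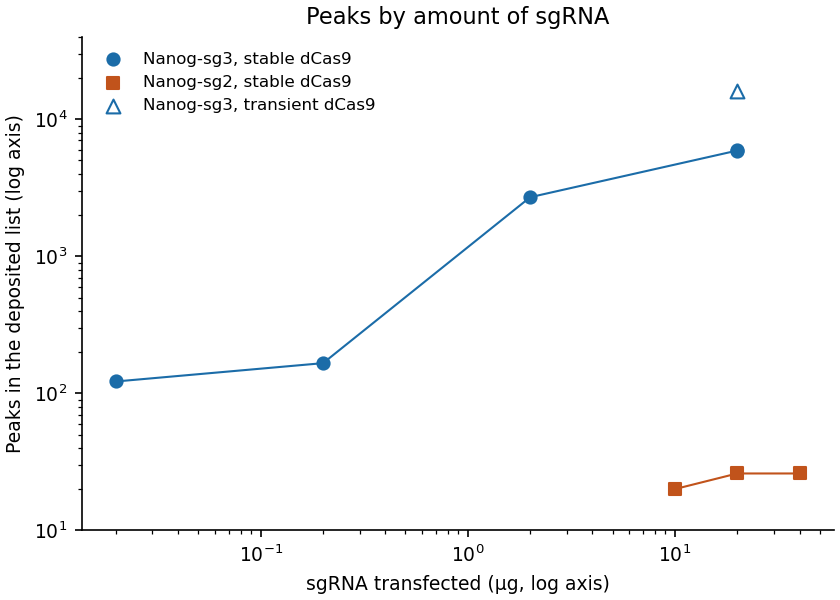
Number of peaks in each deposited list (y axis, log scale) against the sgRNA transfected in ug (x axis, log scale) for Nanog-sg3 and Nanog-sg2; each point is 1 library, the lines join the means, and both Nanog-sg3 libraries at 20 ug (5957 and 5862) are drawn and nearly coincide. Nanog-sg3 goes from 122 to 5862 peaks, and Nanog-sg2 stays between 20 and 26, both after a filter of unstated rule; the numbers in the Nanog-sg3 peak names reach 13697 at 0.02 ug and 15070 in the second 20 ug library.

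Peaks of the 20 ug and 2 ug lists that were present at the next lower dose scored higher than the others. In the library titled 20 ug, peaks also found at 2 ug had a median score of 221.52 against 113.56 for the others, a difference of 107.96 (two-sided permutation test, adjusted p = 2.2e-05), and those also found at 0.2 ug had 473.63 against 132.83. When that list was divided by score into 4 groups of equal size, 63.1% of the highest-scoring group were found at 2 ug (60.6 to 65.6%), falling to 31.7%, 17.8% and 9.49% over the other 3. Of its 100 strongest peaks, 94 were found at 2 ug, 33 at 0.2 ug and 2 at 0.02 ug. Peaks at 2 ug also found at 0.2 ug had 323.10 against 121.24 (permutation adjusted p = 2.2e-05), and those also found at 0.02 ug had 134.65 against 123.44 (permutation adjusted p = 0.55). Within the 0.02 ug list the splits gave no single direction: peaks found at 2 ug had a median score of 81.81 against 86.55 for the rest (permutation adjusted p = 0.55), and the 11 found in the first 20 ug library had 125.92 against 84.42 (permutation adjusted p = 0.0082). Of the 100 strongest peaks at 0.02 ug, 26 were found at 2 ug. Over the 36 such comparisons within the 2 Nanog guides, 28 differences passed an adjusted p of 0.05 and in all 28 the shared peaks scored higher.

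**Figure D3:**
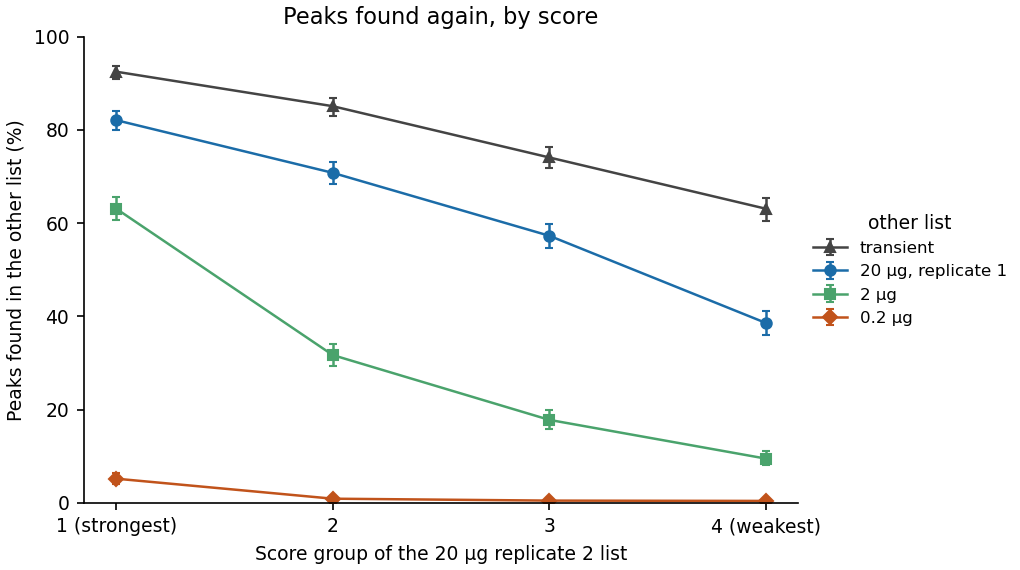
Share of the peaks of the second Nanog-sg3 20 ug library found in 4 other Nanog-sg3 lists (y axis, percent), for 4 equal groups of that library by score, strongest first (x axis); bars are exact 95% intervals for counting error. From the strongest to the weakest group the share falls from 92.5 to 63.1% in the transient list and from 63.1 to 9.49% in the 2 ug list.

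A few positions could be followed through the series. A peak at chromosome 6 between 52167208 and 52168105 was in all 6 Nanog-sg3 IP lists. It scored 196.70 at 0.02 ug (rank 4), 444.32 at 0.2 ug (rank 2) and 1265.05 at 2 ug (rank 2). In the first and second 20 ug libraries it scored 1040.50 (rank 13) and 1183.03 (rank 6), and in the transient library 826.99 (rank 11). The highest peak at 0.2 ug, at chromosome 6 between 53744399 and 53744930 (505.30), was also called at 2 ug, in both 20 ug libraries and in the transient library. The position that scored highest in both 20 ug libraries and in the transient one, chromosome 11 between 119055128 and 119056510 (2376.58, 2173.77 and 2147.38), scored 300.15 at 2 ug, where it ranked 206 of 2698, and had no peak at 0.2 or 0.02 ug. The highest peak at 0.02 ug, at chromosome 17 between 86883653 and 86884137 (245.16), was also called at 2 ug and in the first 20 ug library only.

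The replicate libraries of Nanog-sg3 at 20 ug shared most of their strong peaks and fewer of their weak ones. Of the first library's peaks 61.3% were found in the second (3653 of 5957, 60.1 to 62.6%), and of the second's 62.2% in the first (3646 of 5862, 60.9 to 63.4%), against 29.7 expected from the shifts. Among the 100 strongest peaks, 97 of the first library and 99 of the second were found in the other; the Nanog position was 1 of the 3 missing from the second. Scores of the 3638 peaks paired between the libraries were correlated (Pearson r of log scores 0.66, Spearman rho 0.62, permutation adjusted p = 1.8e-05 for each, the raw p of 1.0e-05 being the smallest possible), and r stayed at 0.66 without the 2 most extreme peaks. These correlations are across peaks, which are not independent replicates; 18 pairs of lists were examined and 13 had a positive rho past an adjusted p of 0.05. The labels do not say whether the 2 libraries came from separate cultures, so their spread may be technical. Their lists also differ in format, as only the second has the sixth column. Of the lowest-scoring group of the 4 in the second library, 38.6% (36.1 to 41.1%) were in the first.

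**Figure D4:**
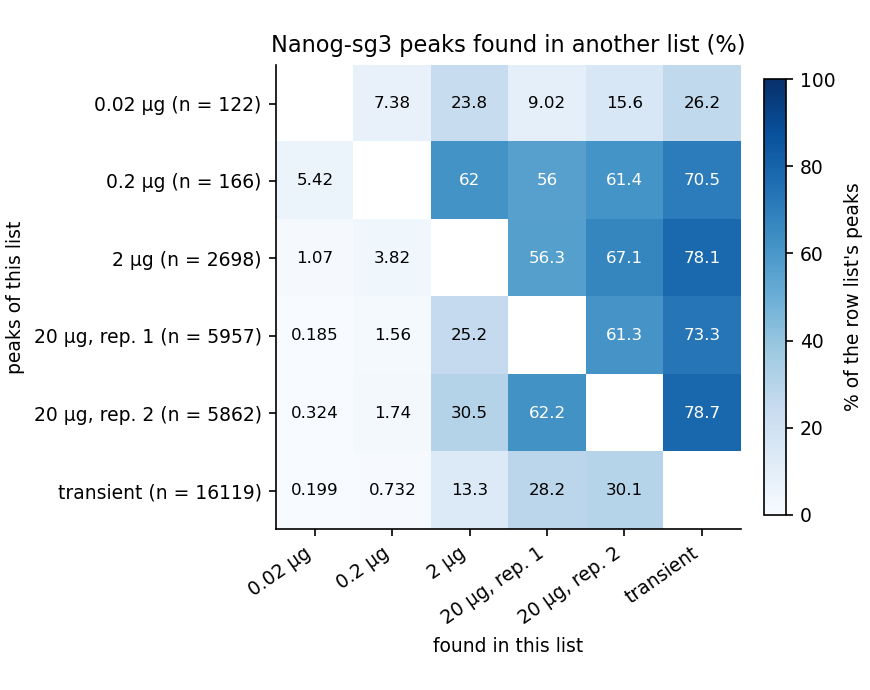
Percent of the peaks of each Nanog-sg3 list (rows, with the number of peaks) that overlap a peak of another list (columns) by at least 1 bp; darker cells are higher shares. The 2 libraries at 20 ug share 61.3 and 62.2%, and the 0.02 ug list shares between 7.38 and 26.2% with the others.

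Nanog-sg3 was also delivered together with a dCas9 plasmid, 20 ug of each, to wild-type V6.5 cells. This transient library gave 16119 peaks, 2.75 times the 5862 of the second stable library. Their median width was 365 bp, against 859 and 946 bp in the first and second stable 20 ug library. Other lists of stable cells had 592 bp (Nanog-sg3 at 2 ug) and 364.5, 641.5 and 885.5 bp (Nanog-sg2 at 40, 20 and 10 ug). Narrow peaks were thus not particular to the transient library. Of the first and the second stable library's peaks, 73.3% and 78.7% overlapped a transient peak by at least 1 bp (95% intervals 72.1 to 74.4% and 77.6 to 79.7%), and so did 99 of the 100 strongest of each. With 50% of both peaks shared, these shares were 30.1% and 33.8%, and with centres within 200 bp 62.5% and 64.5%. Stable peaks found in both 20 ug libraries were in the transient list more often (86.8% of 3646) than those of the second library alone (65.4% of 2216). In the other direction 37.8% of transient peaks were found in either stable library (6098 of 16119, 37.1 to 38.6%), and these scored higher than the rest (median 134.22 against 80.92 by the second library, permutation adjusted p = 2.2e-05). Scores were less alike between the arms than between the stable replicates (rho 0.33 for each stable library against the transient one), a difference that was not tested. The input of the transient cells had 3 peaks, with numbers in the peak names up to 132. With a score of at least 95.15 the ratio of peak numbers was 1.8. No test between the ways of giving dCas9 was made, as the transient arm held 1 library. The numbers in the peak names ran to 24074 in the transient and 15070 in the second stable list, so the ratio is of numbers after a filter of unstated rule.

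The Nanog-sg2 lists held few peaks at any amount: 20 at 10 ug, 26 at 20 ug and 26 at 40 ug. The numbers in the peak names ran to 1431, 1734 and 1945 from 10 to 40 ug, so these counts are after a filter of unstated rule. The listed peaks fell on 40 positions, of which 12 were called at all 3 doses, 8 at 2 doses and 20 at 1. Of the 10 ug peaks 17 of 20 overlapped a 40 ug peak (85%, interval 62.1 to 96.8%), and of the 20 ug peaks 14 of 26 (53.8%, 33.4 to 73.4%). With 50% of both peaks shared, these shares were 35% and 26.9%. Of the 20 positions called at 1 dose, 11 were at 20 ug only, among them the Nanog position. The 20 ug list lacks the sixth column, which holds 11 in the 10 and 40 ug lists. Dose and preparation of the lists thus cannot be told apart. Among positions called at all 3 doses, the highest score was at a different place for each: at 10 ug on chromosome 13 between 81782731 and 81783658 (362.39, with 211.22 at 20 ug and 164.32 at 40 ug), at 20 ug on chromosome 2 between 5060712 and 5061863 (352.90, with 206.58 at 10 ug and 196.94 at 40 ug), and at 40 ug on chromosome 3 between 27168980 and 27170237 (419.14, with 268.02 at 10 ug and 352.11 at 20 ug). At 20 ug the positions on chromosomes 2 and 3 scored nearly the same (352.90 and 352.11). Another position called at all 3 doses was on chromosome 1 between 59305724 and 59306826 (272.32, 195.28 and 177.75 from 10 to 40 ug). Peaks at 20 ug that recurred at 40 ug scored higher than those that did not (145.06 against 84.57, permutation adjusted p = 0.013). The 10 ug peaks found at 20 ug or at 40 ug scored 34.30 and 37.22 above the rest by the median, which did not pass (exact permutation, adjusted p = 0.32 and 0.34). With 40 positions in all, the intervals are wide.

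The deposited peaks of different guides lay at different places, even for guides directed at 1 gene. All 18 pairs of lists of 1 guide overlapped beyond the shifts, and none of the 18 pairs of guides for different genes did, nor any of the 20 pairs of different guides for 1 gene. Phc1-sg1 and Phc1-sg2 shared 2 peaks against 1.41 expected, the Phc1 position and a 49 bp overlap at chromosome 6 near 65028838. Nanog-sg2 at 20 ug and the first Nanog-sg3 library shared 1 peak, the Nanog position. EMX1-sg3 and EMX1-sg1 shared 2 peaks against 11.4 expected, the EMX1 position and chromosome 10 between 60028261 and 60029291, which was fewer than the shifts gave (permutation by shifts, adjusted p = 0.012, one-sided for fewer). Phc1-sg1 shared 6 peaks with the first Nanog-sg3 library against 14.1 expected and 14 with the second against 14.7. With the transient library it shared 15 against 28.2. In the same order, the raw p was 0.014, 0.49 and 0.008 and the adjusted p 0.46, 1 and 0.46 (permutation by shifts, one-sided for fewer). The adjustment ran over 66 mouse pairs, against 6 human pairs for EMX1. Many of the mouse pairs had under 1 overlap expected and so could not pass for fewer. These adjusted values thus do not show that overlaps were as frequent as in the shifts. Counts of shared peaks between guides depend on the authors' filter, whose rule is not given in the sources used here.

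After a filter of unstated rule the control lists held few peaks: 63 in the 293FT no-sgRNA IP, 49 in its input and 3 in the transient input. The numbers in their peak names ran to 2277, 461 and 132. The listed numbers thus do not give the level of background before the filter. The no-sgRNA IP of 293FT cells had its highest score, 90.91, at chromosome 3 between 98062744 and 98063424. The input list had its highest, 231.35, at chromosome 16 between 33973470 and 33976080. Of the EMX1-sg1 and EMX1-sg3 peaks, 44.1% and 43% scored above 90.91, and 7.55% and 8.91% above 231.35. Read depth is unknown, so scores of different lists may not be on 1 scale. No peak of any guide list overlapped a control peak of its build, nor came within 1 kb of one, in 15 pairs of a guide list and a control. The shifts gave at most 0.712 overlaps on average in these pairs, so the absence of overlap was within chance, and a filter on control peaks would give it too.

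Peaks of the EMX1 guides were spread differently over the chromosomes. Chromosomes 17, 19 and 22 together held 23.1% of the EMX1-sg1 peaks (4167 of 18042, 22.5 to 23.7%) and 7.85% of the EMX1-sg3 peaks (67 of 853, 6.14 to 9.87%), and chromosome 4 held 3.19% and 6.57%. The distributions differed (chi-square 212 over 23 chromosomes, Monte Carlo permutation adjusted p = 0.00037 over 11 pairs of lists). The second Nanog-sg3 20 ug library and the transient library differed as well (chi-square 165, adjusted p = 0.00037), and the 20 ug replicates did not differ detectably (15.5, adjusted p = 0.69). The last of these changed under a stricter score: with peaks of at least 95.15 the replicates differed (41.1, Monte Carlo permutation adjusted p = 0.0042). Differences did not follow the guide alone. The second 20 ug and the 2 ug lists of Nanog-sg3 differed (38.2, Monte Carlo permutation adjusted p = 0.013), as did the Phc1 guides (42.1, 0.0071). Phc1-sg1 and Phc1-sg2 did not differ detectably from the second 20 ug library (20.4 and 25.7, 0.46 and 0.26). From the transient library Phc1-sg1 differed (148, 0.00037) and Phc1-sg2 did not detectably (23.5, 0.34). These tests compare libraries and treat peaks as independent.

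**Figure D5:**
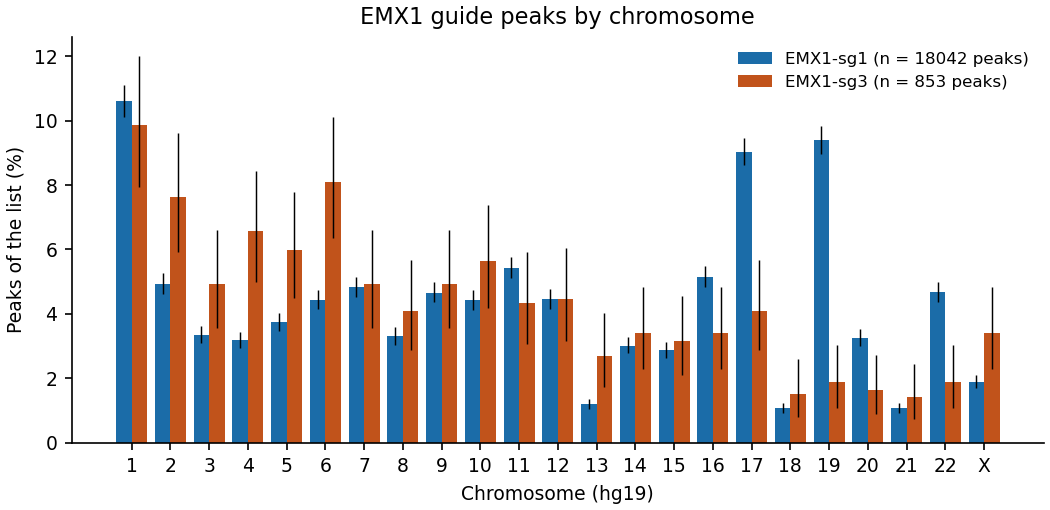
Share of the peaks of EMX1-sg1 (18042 peaks) and EMX1-sg3 (853 peaks) on each chromosome of hg19 (y axis, percent of the list); bars start at 0 and lines are exact 95% intervals for counting error. Chromosomes 17, 19 and 22 hold 9.03, 9.39 and 4.67% of the EMX1-sg1 peaks against 4.1, 1.88 and 1.88% of the EMX1-sg3 peaks.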

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

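Of 202 values recomputed under the alternatives, 167 kept their direction and their side of the threshold or stayed within the allowed range, 30 moved, 4 were no longer past their threshold, 1 passed it and 0 reversed. All 18 pairs of lists of 1 guide overlapped beyond chance under each definition of sharing, under random placement and under both stricter scores, and no pair of different guides did. The shares were judged by that test and not by their size, which was not stable. With 50% of both peaks shared instead of 1 bp, 2 ug peaks found in the second 20 ug library fell from 67.1 to 29.9% and in the first from 56.3 to 24.6%, stable peaks found in the transient list from 73.3 and 78.7 to 30.1 and 33.8%, and Nanog-sg2 peaks found at 40 ug from 85 to 35% (10 ug) and from 53.8 to 26.9% (20 ug). By construction this definition fails for peaks that differ in width more than 2 times. The share of the second 20 ug library in the first stayed at 58.2%. With a score of at least 95.15 the lists held 1596 peaks for Phc1-sg1, 352 for Phc1-sg2, 3524 for the first Nanog-sg3 20 ug library, 7504 for the transient library and 0 for its input, 72 at 0.2 ug, 50 at 0.02 ug, 7303 for EMX1-sg1, 329 for EMX1-sg3, and 0 and 2 for the 293FT no-sgRNA IP and input. With a score of at least 100 the same lists held 1492, 334, 3337, 6978, 0, 59, 41, 6675, 308, 0 and 2 peaks, with 17 for Nanog-sg2 at 20 ug and 1767 for Nanog-sg3 at 2 ug. The ratio of 2 ug to 0.2 ug rose from 16.3 to 25.7 and 29.9 under these scores, and that of the transient to the second stable library fell from 2.75 to 1.8 and 1.75; fewer peaks by construction lowered the counts, and the cause of the changed ratios was not tested. Leaving out each 20 ug replicate put the share of transient peaks found in stable cells at 28.2 to 30.1%, against 37.8% with both. With centres within 200 bp, 3 calls were lost: the score difference of 0.2 ug peaks by the transient list (12.38, permutation adjusted p = 0.065), that of Nanog-sg2 20 ug peaks by the 10 ug list (40.50, permutation adjusted p = 0.12), and rho between Nanog-sg2 at 20 and 40 ug (0.56, permutation adjusted p = 0.087). With a score of at least 95.15 the chromosome difference between the Phc1 guides was lost (chi-square 28.6, adjusted p = 0.1) and one between the 20 ug replicates appeared (41.1, adjusted p = 0.0042); the causes were not tested. Leaving out peaks that overlap control peaks removed 0 peaks and so tested nothing, and ranking by tag count, an FDR limit, and the sequence and gene alternatives were not run. No paired analysis was possible because the groups share no replicate numbers beyond 1. Peak scores and numbers depend on a read depth that is unknown here.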

Other observations

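The tests in this part were chosen only after the results were seen, and 2 of them, those of removed positions and of the weak end, were changed after a first outcome. In mouse cells, peaks were sparse on the X chromosome for every guide with at least 100 peaks: the density on X over that on the autosomes was 0.23 for Phc1-sg1 (95% interval 0.17 to 0.31), 0.37 for Phc1-sg2 (0.21 to 0.60), 0.26 and 0.27 for the 20 ug libraries of Nanog-sg3, 0.21 for the transient one (0.18 to 0.24) and 0.13 at 2 ug (0.08 to 0.19). At 0.2 and 0.02 ug the ratios, 0.18 and 0.38, rest on 2 and 3 peaks on X. No copy number or mappability of X was used here, and the only mouse control list used had 3 peaks. These ratios thus have no background to be compared with, and the cause of the low density was not tested. Of the 49 peaks of the 293FT input list, 15 lay on chromosome 13 (30.6%, interval 18.3 to 45.4%), against 1 of the 63 of the no-sgRNA IP.

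The first pattern is the absence of a peak at the Nanog position from 7 lists of Nanog guides, although it scored 1200.13 and 1472.86 in the other 2. A general loss of strong peaks would have to remove others as well, but 0 of the other 99 strongest peaks of the first 20 ug library were missing from all of the second 20 ug, 2 ug and transient lists (2, 8 and 0 from each alone), and for Nanog-sg2, 0 of the other 10 strongest peaks at 20 ug were missing from both the 10 and the 40 ug list (1 and 0 from each alone). For the 0.2 and 0.02 ug lists, where 67 of those 99 were missing from both, such a loss may be enough. Removal before deposit of positions called with another guide cannot be told apart from other causes. Over 8 pairs of lists of different guides, overlapping peaks were 0.55 times as frequent as in shifted lists, with 7 pairs below the shift mean. Gaps under 1 kb were 2.03 times as frequent, with 0 of the 8 pairs below it. Single pairs ran from 0.17 (EMX1 guides) to 0.91 and 1.39 for overlaps. The 1.39 is of the Phc1 guides, with 2 overlaps against 1.44, and 1 of these is the Phc1 position itself. No mouse pair passed the test for fewer after adjustment over all 66 mouse pairs, many of which could not pass. None of the 8 pairs sets Nanog-sg2 against Nanog-sg3. The peak at the named gene is the first line, out of chromosome order, in the 6 lists that have it. In both EMX1 guide lists it is the only peak with 2 in the sixth column, against 3 elsewhere. The later Nanog lists have no such line, and all 7 have a sixth column, which the 2 Nanog lists with the peak lack. Biological absence of binding at Nanog in single libraries was not tested.

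The second pattern is that listed peaks of different guides lay near each other more often than in shifted lists, while 46 pairs of peaks overlapped against 83.48 in the shifts. At gaps of 1 to 5 kb, 5 of 8 pairs of lists lay above every one of 500 shifts and the EMX1 pair had a ratio of 0.65; at 100 to 500 kb, a range chosen after that outcome, 8 of 8 did, with pairs of peaks 1.68 times as frequent as in the shifts. Segments of a megabase or more with higher copy number or mappability cannot be told apart from local features: the ratio at 1 to 5 kb divided by that at 0.5 to 1 Mb was 1.25 to 1.57 in the 7 mouse pairs and 0.52 in the EMX1 pair, and no mappability or copy number was used here. Shared chromatin accessibility within a cell line was not tested, and the 8 pairs share libraries and are not independent.

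The third pattern is that few peaks of the 0.02 ug list recur at other doses. That every one of its peaks is a chance call is argued against by the 29 peaks found at 2 ug, against at most 3 in any of the shifts. Whether the unshared peaks are the weak end of the shared ones cannot be told apart from other sources: by the 2 ug list, shared peaks scored -4.74 relative to unshared ones (bootstrap 95% interval -20.84 to 13.19), by the first 20 ug library 41.50 (permutation adjusted p = 0.0082) and by the second -9.79 (permutation adjusted p = 0.34), whereas in the 0.2 ug list by 2 ug the difference was 23.08 (6.94 to 41.90). The rule for this test first gave exclusion and was then made stricter, requiring the interval to exclude 0. Peaks unrelated to the guide that passed the filter may make up part of the list, whose names run to 13697 for 122 peaks; the mouse no-sgRNA list that would test this was not analysed here.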
